A study of Mus musculus with 18 samples.

How the data were processed

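Total RNA from 18 samples of CGR8 cells, a mouse embryonic stem cell line of strain 129P2/Ola, was measured on Illumina Mouse-6 version 2 BeadChips, which carry 1 fluorescence colour per array. The labels do not say whether replicates were separate cultures or separate dishes of the same culture, so p-values measure the spread between these samples, which may be partly technical. RNA was isolated with Trizol, cleaned on columns with DNase I and amplified into biotinylated cRNA, per the labels' protocols. The arrays fall into 6 groups of 3. Each group is 1 of 3 stable cell lines, carrying a tetracycline (Tc) inducible siRNA against EGFP or against 1 of 2 sites in nucleolin (lines called Ncl-1 and Ncl-2), kept with or without Tc for 3 days.

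The authors deposited a table of probe intensity that was not normalized between arrays, with values below 0 and a detection p-value for each probe and array. Per the submitters' processing notes, probes were summarised with GenomeStudio 2010.1. Which background option was used is not given in the sources used here. The authors also deposited a second intensity table, normalized by a method not given in the sources used here and kept on a linear scale. Within every array its values had the same rank order as the first table. Its medians were 7.55 to 7.59 on the 12 arrays of replicates 1 and 2 and 9.95 to 9.99 on the 6 arrays of replicate 3, so replicate 3 had been scaled apart. Its exact transformation stays unknown, and it served only as an alternative.

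Starting from the non-normalized intensities of all 18 arrays, background was corrected with limma 3.58.1 (normexp, with negative control levels inferred from the detection p-values, offset 16), followed by quantile normalization and log2, in R 4.3.3. A probe was kept when its detection p was below 0.05 on all 3 arrays of at least 1 group, which left 19154 of 45281 probes. GEO's platform annotation gave 34885 probes 1 gene symbol, 18 probes several and 10378 none. Of the named probes, 34807 had a gene identifier found in a RefSeq gene table of assembly GRCm38.p6, and no symbol needed updating. That table was used for names only and no coordinates are given. Among the kept probes, 16370 carried 1 symbol and 2784 did not. Each gene was represented by its kept probe of highest mean signal over all arrays, giving 10557 genes. For 3998 genes several probes were kept, and in the fit with the replicate number as a block their probes were called in both directions for 6 genes in the Ncl-1 line and 10 genes in the Ncl-2 line. No 2 arrays were duplicates. Between 18099 and 21015 probes per array (40.0% to 46.4%) were detected, and the number of arrays limits the precision of every value.

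One linear model with 6 group means was fitted to the 18 arrays with limma (lmFit, contrasts.fit, eBayes), so that all groups share 1 estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the 10557 genes and a threshold of 0.05. Changes are given as log2 differences ± the standard error of the fit. The contrasts were +Tc against -Tc in each line, the mean response of both nucleolin lines minus the EGFP response, the Ncl-1 minus the Ncl-2 response, and each nucleolin line against the EGFP line without Tc. Where a probe was not detected on any array of a group, the change is given as a bound ("at least N-fold"), the detected group's mean against the dim group's mean with each of its arrays set to the lowest signal detected on that array, or to the probe's own signal if that was higher.

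Before the data were examined, 28 gene lists were fixed. The 21 pathway lists covered p53 targets, pluripotency, LIF and BMP response, two-cell-stage genes, Pol I transcription, ribosome biogenesis, cytosolic ribosomal proteins, Myc targets, DNA replication, mitosis, histones, apoptosis, interferon response, integrated stress and unfolded protein response, oxidative stress, heat shock proteins, hypoxia and glycolysis, the respiratory chain, mitochondrial ribosomal proteins, sterol biosynthesis and imprinted genes. The 7 cell type lists covered primitive endoderm, trophectoderm, mesoderm, epiblast, neuroectoderm, fibroblast or feeder cells and germ cells. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists within a contrast, and again with a correlation estimated per list. Genes named here follow a rule also fixed at that time. It takes Ncl, 6 further fixed genes (Cdkn1a, Mdm2, Nanog, Pou5f1, Sox2 and Npm1), the genes of largest change past the threshold whose groups do not overlap in each contrast, and from each list the 4 members of smallest p in the nucleolin minus EGFP contrast. Trp53 itself was also in the rule and was not analysed here.

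The replicate numbers of the labels were checked for pairing. Deviations from the group means correlated positively in all 45 pairs of arrays with the same number (r from 0.298 to 0.958, median 0.715), against a median of -0.40 over 90 pairs with different numbers, and all 18 arrays were closest to an array of their own number. The first principal component held 45.6% of the variance, and on it the 6 arrays of replicate 3 lay at 31.5 or higher and the other 12 at -4.55 or lower. The numbers therefore pair the samples, and the fit with replicate number as a block is given beside a result named in the text where it changes its call or moves its count by more than 1.5 times. Names of the chips were not used here, so chip could not be tested as a batch.

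The procedure was tested on simulated data for the Ncl-1 comparison over 10557 genes, with 50 genes changed at each size. Without the block it recovered 2% of 1.5-fold, 26% of 2-fold, 62% of 4-fold and 90% of 8-fold changes with 0 false calls among 10323 unchanged genes. With the block it recovered 18%, 74%, 94% and 100%, with 7 false calls. The simulated replicate effect was the same in all groups and the noise had the spread of the blocked fit, so the blocked model held by construction. In the data that effect differed between lines. On the first component replicates 1 and 2 lay at -17.5 and -17.5 in the uninduced EGFP line and -38.1 and -4.55 in the uninduced Ncl-1 line. The simulation therefore does not show how many blocked calls are false in the data. Alternatives planned before the data were examined changed the background correction, its offset, the normalization, the detection filter, the use of 1 probe per gene, a 1.5-fold minimum, the block, array weights, the prior variance, the arrays entering the fit, the list test, and left out each array in turn. The fits with 1 array left out had no block, so the replicate numbers were no longer balanced between the groups. Shifts in these fits may therefore also follow the difference between replicates. Alternatives chosen after seeing the data were a batch term for replicate 3, the use of replicates 1 and 2 alone with and without the block, a line-by-replicate block, and the authors' table with the block.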

Results

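Genome-wide transcript levels were measured in CGR8 mouse embryonic stem cells in which nucleolin (Ncl), an abundant nucleolar RNA-binding protein, was depleted by either of 2 inducible siRNAs. Cells with an inducible siRNA against EGFP, a gene that mouse cells lack, served as the control for induction. The design asks which genes respond to loss of nucleolin. There were 18 arrays, 3 for each of the 3 lines with and without Tc. Mean raw intensity per array ranged from 280 to 837 units, with the 6 arrays of replicate 3 between 625 and 837. These 6 arrays also lay apart on the first principal component, while the +Tc arrays of both nucleolin lines lay at 26.5 or higher on the second component (28.7% of the variance) and all other arrays at -1.02 or lower.

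**Figure D1:**
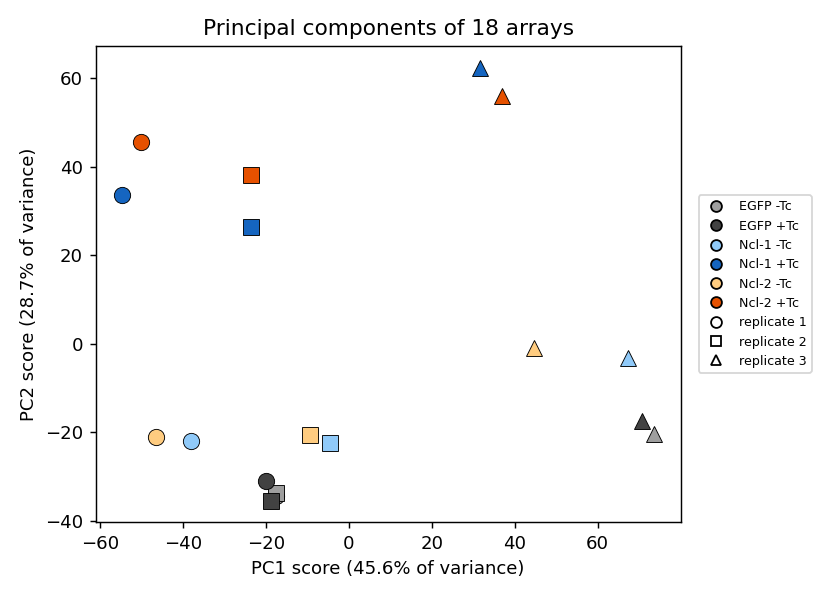
Principal component scores of the 18 arrays (x axis, first component, 45.6% of variance; y axis, second component, 28.7%), coloured by group and with a marker shape per replicate number. Replicate 3 arrays lie at 31.5 or higher on the first component, and the 6 +Tc arrays of the nucleolin lines at 26.5 or higher on the second.

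The targeted transcript fell in both nucleolin lines. Ncl (Entrez Gene 17975) had a log2 signal of 11.71 ± 0.45 (SD, n = 3) in the Ncl-1 line without Tc and 7.03 ± 0.52 with Tc. In the Ncl-2 line it had 11.36 ± 0.42 and 6.99 ± 0.51. The log2 change was -4.67 ± 0.36 (SE) in the Ncl-1 line (limma adjusted p = 2.2e-06) and -4.37 ± 0.36 in the Ncl-2 line (adjusted p = 4.2e-06), leaving 3.92% and 4.83% of the signal. In the EGFP line Ncl changed by 0.07 ± 0.36, within the error. A dimmer Ncl probe gave -4.80 ± 1.06 (adjusted p = 0.0134) and -4.47 ± 1.06 (adjusted p = 0.0188), with the larger error following a gap of 2.39 between its replicate 3 and its other arrays.

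**Figure D2:**
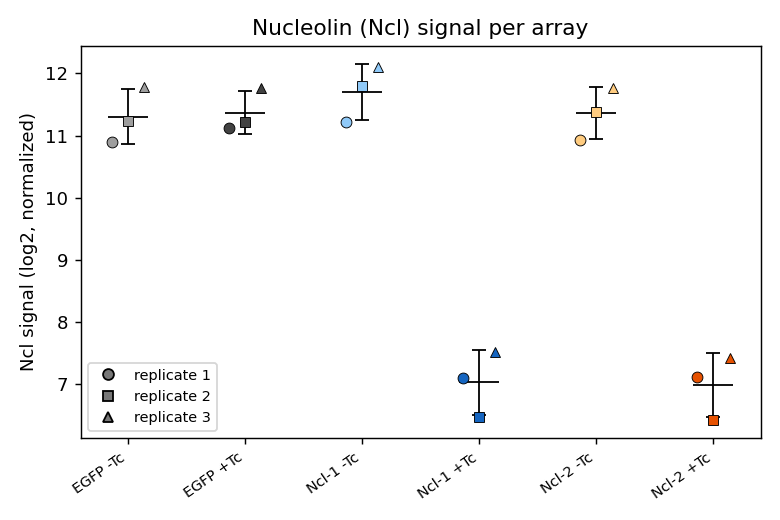
Normalized log2 signal of Ncl on each array (y axis) by group (x axis), with dashes for group means and bars for 1 SD (n = 3). The 6 +Tc arrays of the nucleolin lines lie between 6.42 and 7.52 and the other 12 between 10.9 and 12.1.

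Induction of the EGFP siRNA brought no gene past the threshold. limma called 0 of 10557 genes in the EGFP line, with 13 at an unadjusted p below 0.05 where 528 would be expected by chance, and 0 (75 unadjusted) with the replicate block. With both counts far below 528 the tests were conservative for this line, so small changes may have been missed. The largest change of any gene was 0.757 on the log2 scale. Fas, a death receptor gene, and Dppa3, a gene of the oocyte and early embryo, both had a change of -0.00, and Mdm2, which encodes the ubiquitin ligase of p53, had 0.03. None of the 28 lists passed the test (lowest adjusted p = 0.294), although between 0 and 4 lists passed when 1 array was left out. The counts above 0 came without EGFP -Tc replicates 1, 2 or 3 or EGFP +Tc replicates 2 or 3, with the 4 lists arising without EGFP -Tc replicate 2. With 1 array left out and no block, such calls may also follow the difference between replicates.

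Induction of the first nucleolin siRNA was followed by large rises and falls of single genes. Cpz, a secreted carboxypeptidase, rose by 4.87 ± 0.34 on the log2 scale (SE, n = 3 per group, limma adjusted p = 1.3e-06) and Ms4a10 by 4.74 ± 0.38 (adjusted p = 3.3e-06). Fas rose by 3.82 ± 0.23 (adjusted p = 4.5e-07), Matn1, a cartilage matrix protein, by 3.94 ± 0.28 and Casp14, a caspase of the epidermis, by 3.86 ± 0.29. The hormone gene Sct rose by 3.81 ± 0.68 and the melanocyte gene Mlana by 3.49 ± 0.55, and Snx20 was at least 8.62-fold higher with Tc (adjusted p = 1.9e-05). Among falling genes, Chac1, which degrades glutathione and is a target of the integrated stress response, fell by 3.78 ± 0.32 (adjusted p = 5.3e-06). Nupr1, a stress-induced nuclear protein, fell by 3.17 ± 0.64 (adjusted p = 0.006). Also lower were Fgf17 (-3.02 ± 0.53), Ubap1l (-2.84 ± 0.50), the homeodomain gene Hopx (-2.48 ± 0.40), Notum, a secreted inhibitor of Wnt proteins (-2.30 ± 0.37), and the acyl-CoA thioesterase Acot7 (-2.27 ± 0.28). In all, 857 genes passed the threshold, 568 higher and 289 lower, and 704 of these changed at least 2-fold. With the replicate block the count was 2819 (1501 higher, 1318 lower). Without Ncl-1 -Tc replicate 2 the count was 525.

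Targets of the tumour suppressor p53 rose together in the Ncl-1 line. Of 34 measured members 13 rose and 1, the D-type cyclin Ccnd2, fell, while 18 rose and 1 fell when adjusted over the list alone and 23 rose with the replicate block. Besides Fas, Mdm2 rose by 2.30 ± 0.29 (adjusted p = 0.00015), the apoptosome gene Apaf1 by 1.81 ± 0.27 (adjusted p = 0.00062) and Trp53inp1 by 1.43 ± 0.23 (adjusted p = 0.001). The cell cycle inhibitor Cdkn1a rose by 1.73 ± 0.38 (adjusted p = 0.0095). The list's median change was 1.10 (camera adjusted p = 6.7e-11, and adjusted p = 0.0037 with an estimated correlation), with 0.98 in replicates 1 and 2 and 1.18 in replicate 3. The Ccnd2 change of -1.05 ± 0.29 (adjusted p = 0.0365) lost its call without Ncl-1 -Tc replicate 1 (0.13), Ncl-1 -Tc replicate 2 (0.098), Ncl-1 +Tc replicate 1 (0.099), Ncl-1 +Tc replicate 2 (0.12), EGFP +Tc replicate 1 (0.0503) or EGFP +Tc replicate 2 (0.0501).

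The lists of DNA replication, of the integrated stress and unfolded protein response and of sterol biosynthesis shifted downward in the Ncl-1 line. Of 42 measured replication genes 3 fell and 0 rose (3 adjusted over the list alone, 15 with the block), namely the E-type cyclin genes of S phase entry, Ccne1 (-1.74 ± 0.30, adjusted p = 0.0018) and Ccne2 (-1.72 ± 0.37, adjusted p = 0.0084), and Pola2, a subunit of DNA polymerase alpha (-0.94 ± 0.19, adjusted p = 0.0065). The list's median was -0.41 (adjusted p = 0.00011, and adjusted p = 0.0108 with an estimated correlation). Of 34 genes of the integrated stress and unfolded protein response 10 fell and 0 rose (11 adjusted over the list alone, 14 lower and 2 higher with the block), with a median of -0.44 (adjusted p = 5.2e-05, and adjusted p = 0.0108 with an estimated correlation). Besides Chac1 and Nupr1 these included Herpud1, a component of ER-associated degradation (-1.55 ± 0.21), the mitochondrial folate enzyme Mthfd2 (-1.76 ± 0.28) and Aldh18a1, an enzyme of proline synthesis (-1.81 ± 0.35). Of 21 genes in the sterol biosynthesis list 2 fell (3 adjusted over the list alone, 10 with the block). These were Scd2, a fatty acid desaturase rather than a sterol enzyme (-1.79 ± 0.31, adjusted p = 0.0019), and the squalene epoxidase Sqle (-0.82 ± 0.24, adjusted p = 0.0496). The Sqle call was lost without any array but Ncl-1 +Tc replicate 2, Ncl-2 -Tc replicates 1 and 3 and Ncl-2 +Tc replicate 3 (adjusted p = 0.205 without Ncl-1 +Tc replicate 3). The sterol list's median was -0.53 (adjusted p = 0.0008, and adjusted p = 0.0327 with an estimated correlation). In replicates 1 and 2 these medians were -0.29, -0.36 and -0.47, and in replicate 3 they were -0.73, -0.55 and -0.75. The stress response median was -0.69 without Ncl-1 -Tc replicate 1, -0.23 without Ncl-1 -Tc replicate 3 and -0.77 without Ncl-1 +Tc replicate 3. These fits had no block, so leaving out 1 array also unbalanced the replicates between the groups. With both the block and an estimated correlation only the p53 list kept its call (adjusted p = 0.0259), against 0.135 for the replication and stress response lists and 0.339 for the sterol list.

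The remaining called lists passed the preset test in the Ncl-1 line and lost the call with an estimated correlation. Two-cell-stage genes, transcribed at the activation of the embryonic genome, had a median of 1.40 (adjusted p = 0.00011, and adjusted p = 0.406 with an estimated correlation), with a median change of 1.29 in replicates 1 and 2 and 1.34 in replicate 3. The list's median signal was higher with Tc by 0.52, 0.32 and 2.19 in replicates 1, 2 and 3. The median change was 0.60 without Ncl-1 +Tc replicate 3, 0.92 without Ncl-1 -Tc replicate 1 and 0.80 with no filter on detection, and its range over all alternatives was 0.60 to 2.03. Of 13 measured members 2 rose (6 adjusted over the list alone, 7 with the block), Dppa3 by 2.37 ± 0.43 (adjusted p = 0.0026) and Tcstv1 by 2.57 ± 0.66 (adjusted p = 0.0243). The count of 2 was 1 without Ncl-1 -Tc replicates 1 or 2 or Ncl-1 +Tc replicate 3, 5 without Ncl-1 +Tc replicate 2 and 6 without Ncl-1 -Tc replicate 3. The Tcstv1 call was lost without Ncl-1 -Tc replicate 1 (adjusted p = 0.091), Ncl-1 -Tc replicate 2 (0.12) or Ncl-1 +Tc replicate 3 (0.11), and its probe cannot be told from near-identical copies. Trophectoderm genes had a median of 0.30 and a mean of 0.85 (adjusted p = 0.0107, and adjusted p = 0.406 with an estimated correlation), and 3 of 13 rose (4 adjusted over the list alone). These were Krt7, a simple-epithelial keratin, by 3.44 ± 0.47, the transcription factor gene Tfap2c by 2.90 ± 0.46, and the growth factor gene Igf2 by 3.19 ± 0.82 (adjusted p = 0.024). The Igf2 call was lost without Ncl-1 -Tc replicate 1 (0.082), Ncl-1 -Tc replicate 2 (0.094) or Ncl-1 +Tc replicate 3 (0.10). The trophectoderm median was -0.06 in replicates 1 and 2 (adjusted p = 0.16) and 1.01 in replicate 3, and the call was lost without Ncl-1 +Tc replicate 3 (median 0.06, adjusted p = 0.169). That median was 0.67 without Ncl-1 +Tc replicate 1, 0.47 with no background correction, 0.12 with no filter on detection and 0.01 with detection p under 0.01 (adjusted p = 0.265). Histone genes had a median of 0.64 (adjusted p = 0.00017, and adjusted p = 0.571 with an estimated correlation), with 0.23 in replicates 1 and 2 (adjusted p = 0.073) and 1.56 in replicate 3. Of these 48 genes H4c2 rose (1.54 ± 0.45, adjusted p = 0.049, a call lost without any array but EGFP -Tc replicate 3, EGFP +Tc replicates 2 and 3 and Ncl-2 +Tc replicate 3, with 0.19 without Ncl-1 -Tc replicate 3), or 0 adjusted over the list alone and 14 with the block. Their sequences overlap, and the list's call was lost without Ncl-1 +Tc replicate 3 (adjusted p = 0.0613). Instead of 1, the histone count was 2 without EGFP -Tc replicate 3 or Ncl-1 -Tc replicate 1 and 3 without EGFP +Tc replicate 3. The histone median was 0.39 without Ncl-1 -Tc replicate 3 and 0.23 with array weights. Ribosome biogenesis genes had a median of -0.33 (adjusted p = 0.0489, and adjusted p = 0.408 with an estimated correlation), and 0 of 51 members passed limma's threshold in either direction, adjusted over all genes or over the list alone. With the block 10 of them were lower and 1 was higher, and the median was -0.39 in replicates 1 and 2 and -0.19 in replicate 3. The list's call was lost without EGFP +Tc replicate 1 (adjusted p = 0.0501), Ncl-1 -Tc replicate 2 (0.195, median -0.22), Ncl-1 -Tc replicate 3 (0.0542), Ncl-1 +Tc replicate 1 (0.271), Ncl-2 -Tc replicate 2 (0.0505) or Ncl-2 +Tc replicate 2 (0.0502).

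The core pluripotency genes did not pass the test as a group in the Ncl-1 line. Nanog changed by -0.08 ± 0.77 (adjusted p = 0.98), Pou5f1 by -0.25 ± 0.54 (adjusted p = 0.888) and Sox2 by 0.80 ± 0.63 (adjusted p = 0.568, and 0.0043 with the block). Of 30 pluripotency genes Dppa3 rose and Lin28a, an inhibitor of let-7 processing, fell by 1.36 ± 0.29 (adjusted p = 0.0079), and the list's median was -0.18 (adjusted p = 0.478). Npm1, another abundant nucleolar protein, changed by -0.11 ± 0.18 (adjusted p = 0.855). Among the heat shock proteins Hspa1a rose by 2.01 ± 0.35, the collagen chaperone Serpinh1 by 1.71 ± 0.31 and Cryab by 2.57 ± 0.52, and with Hspb8 4 of 17 were higher, while the list's median was -0.12, its mean 0.26 and its test upward (adjusted p = 0.214). Of 18 mesoderm genes 4 rose and 3 fell (median 0.03, adjusted p = 0.478), with Wnt5a (3.18 ± 0.34), Wnt3a (3.11 ± 0.46), Lhx1 and Gsc higher and Lmo2 (-1.82 ± 0.22), Meox1 (-1.67 ± 0.24) and Isl1 lower. Of 12 epiblast genes Cldn6 (2.10 ± 0.31), Nodal (1.32 ± 0.27) and Wnt8a rose and Fgf15 and Lef1 fell (median 0.06, adjusted p = 0.806). Of 11 neuroectoderm genes Gbx2 (-1.39 ± 0.27), Meis2, Stmn2 and Sox11 fell (median -0.61, adjusted p = 0.109). Of 14 imprinted genes Igf2 rose and Phlda2, Dlk1 and the growth restrainer Grb10 (-1.58 ± 0.23) fell (median -0.08, adjusted p = 0.478). Lhx1, Gsc, Isl1, Lef1 and Dlk1 were chosen after their values were seen. With the block 2 pluripotency genes were higher and 3 lower, 4 and 3 heat shock proteins, 3 and 5 neuroectoderm genes, and 2 and 4 imprinted genes. The calls of Wnt8a (adjusted p up to 0.0786) and Fgf15 (0.117) were lost without Ncl-1 -Tc replicates 2 or 3 or Ncl-1 +Tc replicates 1 or 3. Stmn2 (0.0858) lost its call without Ncl-1 -Tc replicate 3 or Ncl-1 +Tc replicate 3. The arrays for Igf2 are given above. Phlda2 (0.103) lost its call without Ncl-1 -Tc replicates 1 or 2 or any Ncl-1 +Tc array. Hspb8 (0.189) lost its call without any array of the Ncl-1 line but -Tc replicate 3. It also lost it without EGFP -Tc replicate 1, EGFP +Tc replicate 1, Ncl-2 -Tc replicate 2 or Ncl-2 +Tc replicates 1 or 2. Sox11 (0.174) lost it without any array but Ncl-1 +Tc replicates 1 and 2 and Ncl-2 +Tc replicates 2 and 3.

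No other list passed the test in the Ncl-1 line. The medians were -0.25 for Myc targets (Mthfd2, Shmt2 and Ccnd2 lower of 25, adjusted p = 0.0851), 0.46 for primitive endoderm (Krt19 higher of 20, adjusted p = 0.158) and -0.22 for mitosis (0 of 33, adjusted p = 0.302). They were 0.03 for LIF and BMP response (Id2 higher of 19, adjusted p = 0.967), 0.04 for interferon response (Usp18 and Xaf1 higher and Ddx58 lower of 20, or 5 and 2 adjusted over the list alone, adjusted p = 0.478) and 0.18 for fibroblast genes (Ccn1, Ccn2 and Mmp2 higher and Tgfbi lower of 14, adjusted p = 0.608). Cytosolic ribosomal proteins had a median of 0.09 (0 of 50, adjusted p = 0.625), mitochondrial ribosomal proteins -0.09 (Mrpl12 lower of 71, adjusted p = 0.473) and the respiratory chain 0.13 (0 of 43, adjusted p = 0.478). Hypoxia and glycolysis genes had -0.24 (P4ha2 and Ddit4 higher of 25, adjusted p = 0.478) and oxidative stress genes 0.01 (0 of 24, adjusted p = 0.945). For Pol I transcription the median was 0.01 but the mean -0.15 and the test downward (Taf1d lower of 23, adjusted p = 0.478). For apoptosis regulators the median was -0.13 but the mean 0.05 and the test upward (Apaf1 higher of 22, adjusted p = 0.967), and for germ cell genes they were -0.05 and 0.06, also upward (Dppa3 higher of 12, adjusted p = 0.508). With the block the higher and lower counts were 2 and 4 for Myc targets, 5 and 1 for primitive endoderm, 0 and 3 for mitosis, 2 and 2 for LIF and BMP response, 5 and 2 for interferon response and 4 and 3 for fibroblast genes. They were 0 and 2 for cytosolic and 0 and 3 for mitochondrial ribosomal proteins, 1 and 2 for the respiratory chain, 2 and 2 for hypoxia, 3 and 1 for oxidative stress, 1 and 6 for Pol I transcription, 4 and 4 for apoptosis regulators and 2 and 2 for germ cell genes. Among the genes named for these lists, Ccn1 was chosen after its values were seen. The calls of Id2 (adjusted p up to 0.0952), Ddx58 (0.12) and Ddit4 (0.116) were lost without Ncl-1 -Tc replicates 2 or 3 or Ncl-1 +Tc replicates 1 or 3. Ccn2 (0.0616) lost its call without Ncl-1 -Tc replicate 1 or Ncl-1 +Tc replicate 3. Mmp2 (0.0817) lost it without Ncl-1 -Tc replicate 2 or Ncl-1 +Tc replicates 1 or 2. Tgfbi (0.115) lost it without Ncl-1 -Tc replicates 2 or 3 or Ncl-1 +Tc replicate 1. Mrpl12 (0.127) lost it without Ncl-1 -Tc replicates 1 or 2 or any Ncl-1 +Tc array. Krt19 (0.122) lost it without any Ncl-1 -Tc array or Ncl-1 +Tc replicates 2 or 3. Usp18 (0.151) lost it without Ncl-1 -Tc replicates 1 or 2, Ncl-1 +Tc replicates 1 or 3, EGFP -Tc replicate 2, EGFP +Tc replicate 1 or Ncl-2 +Tc replicate 2. Xaf1 (0.16) lost it without any Ncl-1 -Tc array, Ncl-1 +Tc replicates 1 or 2, EGFP -Tc replicate 1, EGFP +Tc replicate 1 or Ncl-2 -Tc replicate 2. Taf1d (0.127) lost it without Ncl-1 -Tc replicates 1 or 2, any Ncl-1 +Tc array, EGFP -Tc replicate 2, EGFP +Tc replicates 1 or 2 or Ncl-2 -Tc replicate 2. P4ha2 (0.202) lost it without any array but Ncl-1 -Tc replicate 3, Ncl-2 -Tc replicate 3 and Ncl-2 +Tc replicate 3. The arrays for Ccnd2 are those given with the p53 targets. With members that were undetected in 1 of the groups set to their bound, the fibroblast median was 0.05 in place of 0.18, and the medians of the other 27 lists were the same to 2 decimals.

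**Figure D3:**
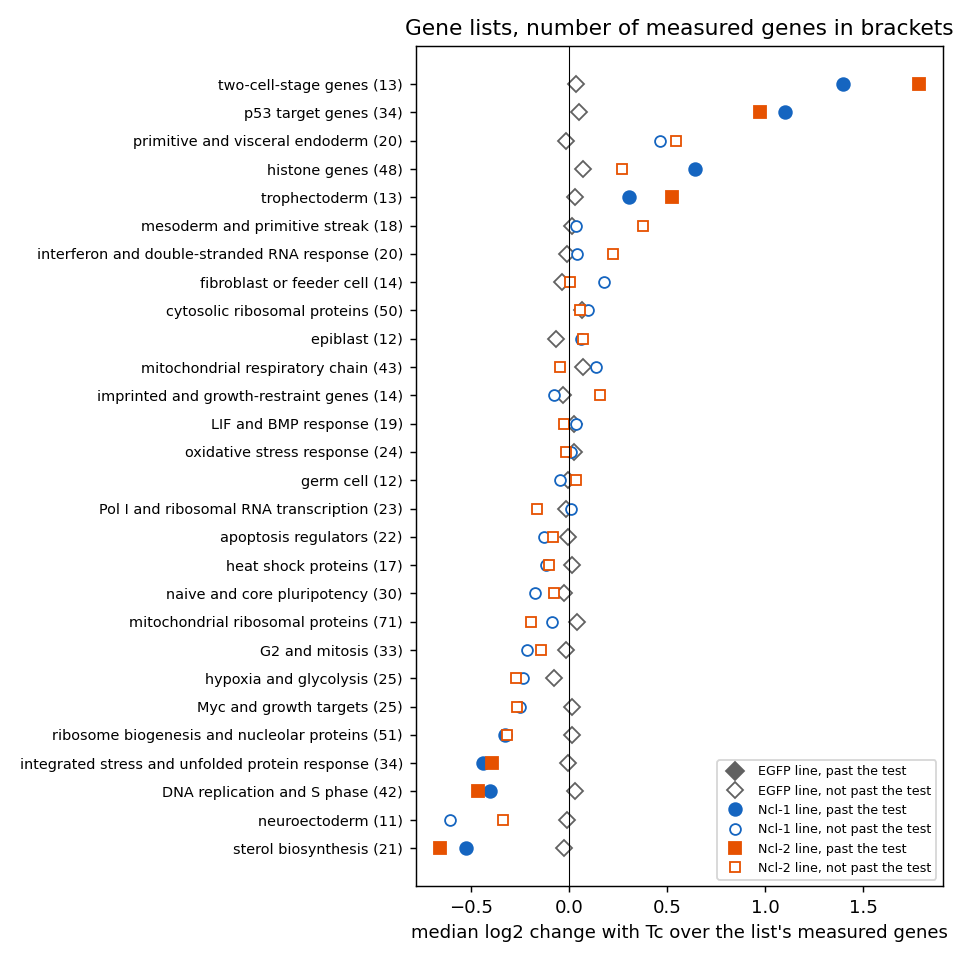
Median log2 change with Tc (x axis) of each of the 28 gene lists (y axis, number of measured genes in brackets) in the EGFP, Ncl-1 and Ncl-2 lines, with filled symbols for lists past the camera test at the preset correlation. The p53 list lies at 1.10 and 0.97 in the nucleolin lines and 0.05 in the EGFP line, which has no filled symbol.

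The second nucleolin siRNA, whose arrays are separate from those of the first, was followed by changes of much the same genes. Ms4a10 rose by 5.08 ± 0.38 (SE, n = 3 per group, limma adjusted p = 1.7e-06), Cpz by 4.73 ± 0.34, Krt7 by 4.09 ± 0.47, Fas by 3.94 ± 0.23 (adjusted p = 2.9e-07), Casp14 by 3.85 ± 0.29 and Snx20 by 3.83 ± 0.34. Dmkn, an epidermal secreted protein, rose by 4.18 ± 0.75 (adjusted p = 0.0022). Chac1 fell by 3.79 ± 0.32 (adjusted p = 6.2e-06), and Cplx1, a regulator of synaptic vesicle release, changed by -2.82 ± 0.27 (adjusted p = 1.2e-05). Also lower were Ubap1l (-3.16 ± 0.50), Nupr1 (-3.13 ± 0.64), Hopx (-2.64 ± 0.40), Fgf17 (-2.54 ± 0.53) and the sarcomere gene Actn3 (-2.52 ± 0.37). In all, 964 genes passed the threshold, 633 higher and 331 lower, and 769 changed at least 2-fold. With the replicate block there were 2842 (1463 higher, 1379 lower). The count was 539 without Ncl-2 +Tc replicate 1 and also fell by more than 1.5 times without Ncl-2 -Tc replicate 2.

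In the Ncl-2 line p53 targets rose again, 13 of 34 with none lower (18 higher and 1 lower adjusted over the list alone, 24 higher and 1 lower with the block). The 13 were 8 without Ncl-2 -Tc replicate 2. Mdm2 rose by 2.43 ± 0.29 (adjusted p = 8.2e-05), Apaf1 by 1.96 ± 0.27 and Trp53inp1 by 1.59 ± 0.23. Cdkn1a rose by 1.49 ± 0.38 (adjusted p = 0.0214), a call lost without Ncl-2 -Tc replicate 2 (0.10), Ncl-2 -Tc replicate 3 (0.056), Ncl-2 +Tc replicate 1 (0.11) or Ncl-2 +Tc replicate 2 (0.057). The p53 median was 0.97 (adjusted p = 5.8e-11, and adjusted p = 0.0036 with an estimated correlation), with 1.09 in replicates 1 and 2 and 0.96 in replicate 3. Replication genes had a median of -0.47 (3 lower of 42, or 4 adjusted over the list alone and 20 with the block, adjusted p = 1.2e-05, and adjusted p = 0.006 with an estimated correlation), with Ccne1 at -1.62 ± 0.30, Pola2 at -1.05 ± 0.19 and Ccne2 at -1.59 ± 0.37. The Ccne2 call (adjusted p = 0.013) was lost without Ncl-2 -Tc replicate 1 (0.051), Ncl-2 -Tc replicate 2 (0.072) or Ncl-2 +Tc replicate 3 (0.055). Stress response genes had a median of -0.40 (10 lower of 34, or 11 lower and 1 higher adjusted over the list alone and 16 lower and 3 higher with the block, adjusted p = 4.9e-05, and adjusted p = 0.0134 with an estimated correlation), with Herpud1 at -1.33 ± 0.21, Mthfd2 at -1.60 ± 0.28 and Aldh18a1 at -2.33 ± 0.35. The sterol list had a median of -0.66 (1 lower of 21, or 3 adjusted over the list alone and 12 with the block, adjusted p = 0.00028, and adjusted p = 0.0198 with an estimated correlation). Its fatty acid desaturase gene Scd2 was at -1.60 ± 0.31. In replicates 1 and 2 these medians were -0.51, -0.45 and -0.63, and in replicate 3 they were -0.38, -0.37 and -0.59. The replication count was 6 without Ncl-1 +Tc replicate 3. The sterol count was 3 without Ncl-1 +Tc replicate 3 or Ncl-2 -Tc replicate 3 and 2 without Ncl-1 -Tc replicate 1. Of the stress response genes 1 was higher without Ncl-1 +Tc replicate 3 and 2 without Ncl-2 +Tc replicate 3. The stress response median was -0.63 without Ncl-2 +Tc replicate 3, and the sterol median -0.43 with array weights. With both the block and an estimated correlation the p53 list had an adjusted p of 0.0251 and these other lists 0.112, 0.138 and 0.259.

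The two-cell-stage and trophectoderm lists also passed the preset test in the Ncl-2 line, and no other list did. Of 13 two-cell-stage genes 6 rose (10 adjusted over the list alone, 10 with the block), among them Dppa3 by 2.28 ± 0.43 (adjusted p = 0.0032) and Tdpoz4 by 2.33 ± 0.52 (adjusted p = 0.0102, but 0.059 without Ncl-2 +Tc replicate 1). Only 1 of the 13 passed without Ncl-2 +Tc replicate 1, 2 without Ncl-2 -Tc replicates 2 or 3 and 3 without Ncl-2 +Tc replicate 2. The call of Tcstv1 was lost without any array of the Ncl-2 line (0.0634 to 0.087) and that of Tmem92 without Ncl-2 -Tc replicates 2 or 3 or Ncl-2 +Tc replicates 1 or 2 (0.0657 to 0.118). The list's median was 1.78 (adjusted p = 1.8e-06, and adjusted p = 0.23 with an estimated correlation), with a median change of 1.86 in replicates 1 and 2 and 1.67 in replicate 3. The list's median signal was higher with Tc by 1.61, 0.37 and 1.74 in replicates 1, 2 and 3. Trophectoderm genes had a median of 0.52 (Krt7, Tfap2c, Ascl2, Igf2 and Rhox9 higher of 13, adjusted p = 0.00084, and adjusted p = 0.23 with an estimated correlation), with 0.87 in replicates 1 and 2 and 0.03 in replicate 3. The 5 were 3 without Ncl-2 -Tc replicate 3 or Ncl-2 +Tc replicate 1. The trophectoderm median was 0.86 without Ncl-2 +Tc replicate 3, 0.84 with no background correction, 0.91 with the authors' table and 0.33 with no filter on detection. Tfap2c rose by 2.82 ± 0.46, while the call of Igf2 was lost without Ncl-2 -Tc replicates 2 or 3 or Ncl-2 +Tc replicates 1 or 2 (adjusted p from 0.0649 to 0.139). That of Rhox9 was lost without Ncl-2 -Tc replicates 1 or 3 or Ncl-2 +Tc replicates 1 or 3 (from 0.0555 to 0.126). Ribosome biogenesis genes had a median of -0.32 (0 of 51 by limma, adjusted p = 0.0671), which passed with the block (13 lower and 1 higher, adjusted p = 0.0028), and so did mitochondrial ribosomal proteins at -0.20 (1 lower of 71, adjusted p = 0.10, and 7 lower and 0.0474 with the block). Neither held with an estimated correlation (adjusted p = 0.348 and 0.748, and adjusted p = 0.399 and 0.90 with the block as well). Histone genes had 0.27 (0 of 48, 1 higher with the block, adjusted p = 0.12), heat shock proteins -0.10 with a mean of 0.37 (4 higher of 17, adjusted p = 0.118) and mesoderm genes 0.38 (4 higher and 3 lower of 18, 8 and 3 with the block, adjusted p = 0.119). Nanog changed by 0.22 ± 0.77 (adjusted p = 0.952), Sox2 by 0.60 ± 0.63 (adjusted p = 0.732, and 0.023 with the block), Npm1 by 0.03 ± 0.18, and Pou5f1 by -0.53 ± 0.54 (adjusted p = 0.719, and 0.041 with the block). The pluripotency list's median was -0.08 (adjusted p = 0.297), and among the uncalled lists the adjusted p ranged from 0.0671 to 0.976. Setting undetected members to their bound changed the germ cell median from 0.04 to 0.08 and left the other medians the same to 2 decimals.

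**Figure D4:**
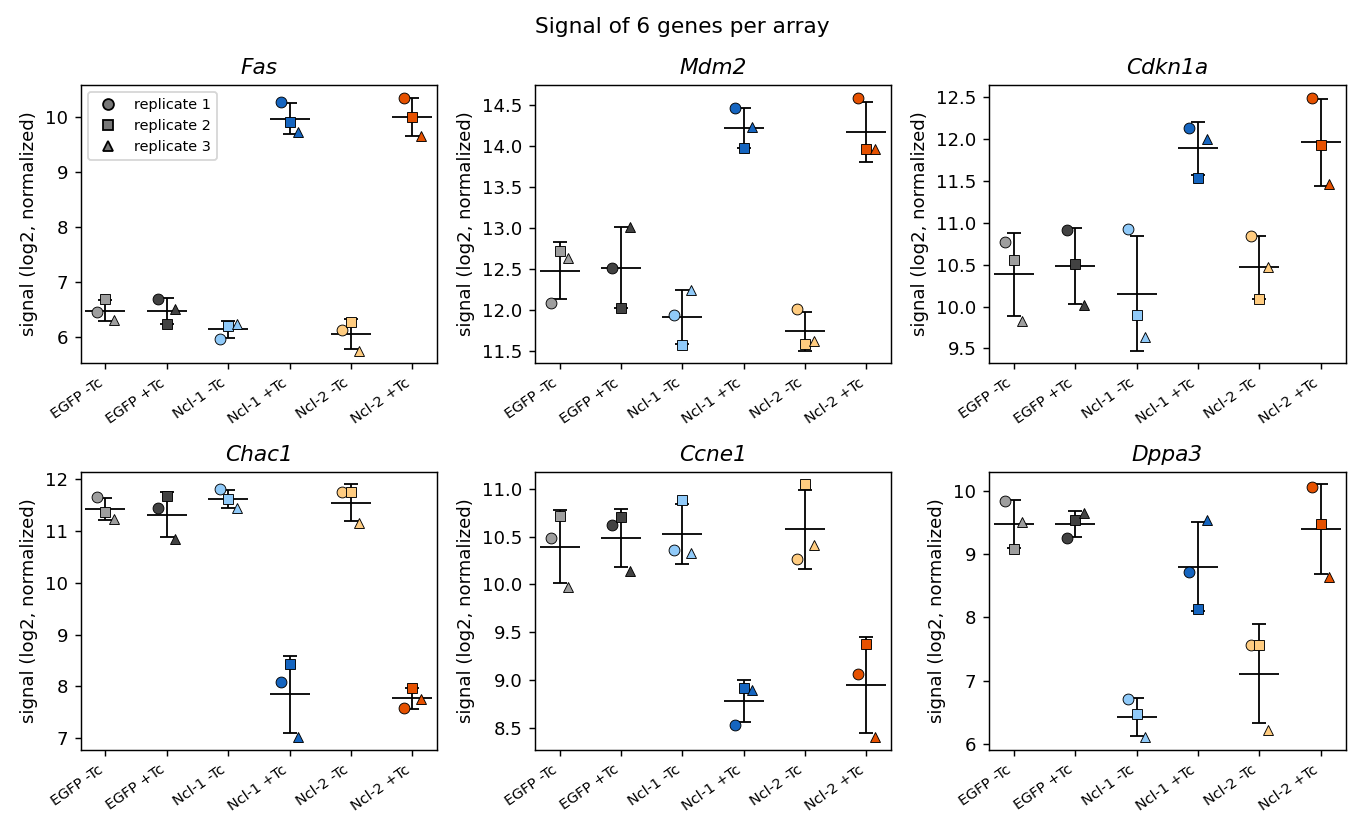
Normalized log2 signal of Fas, Mdm2, Cdkn1a, Chac1, Ccne1 and Dppa3 on each array (y axes) by group (x axes), with dashes for group means and bars for 1 SD (n = 3). Fas has group means of at least 9.97 in the +Tc nucleolin arrays and at most 6.49 elsewhere, while Dppa3 has 9.48 in both EGFP groups and 6.43 and 7.11 in the uninduced nucleolin lines.

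The responses of both nucleolin lines overlapped. Of the called genes 686 changed the same way in both lines, 476 higher and 210 lower, where independent lists would share 34.1 and 9.06, and 0 changed in opposite ways. With the block 1988 were shared (expected 208 higher and 172 lower) and 2 were opposite. Without Ncl-2 -Tc replicate 2 the shared count was 454. Across genes, which are not independent replicates, the log2 changes of the lines correlated with r = 0.892, against 0.195 and 0.129 with the EGFP line. Fas, Cpz, Chac1 and Ncl itself were among the shared genes. limma called 0 genes for a difference between the Ncl-1 and Ncl-2 responses, with 41 at an unadjusted p below 0.05 and 0 (299 unadjusted) with the block. The 171 genes called in the Ncl-1 line alone and the 278 in the Ncl-2 line alone are therefore not shown to differ. Both unadjusted counts were below the 528 expected by chance, so this test was conservative and differences may have been missed. Of the lists, histone genes were higher in the Ncl-1 response by a median of 0.33 (adjusted p = 5.8e-05, and adjusted p = 0.876 with an estimated correlation) and respiratory chain genes by 0.14 (adjusted p = 0.0487, and adjusted p = 0.876 with an estimated correlation, or 0.109 with the block), with 0 members called in either list.

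**Figure D5:**
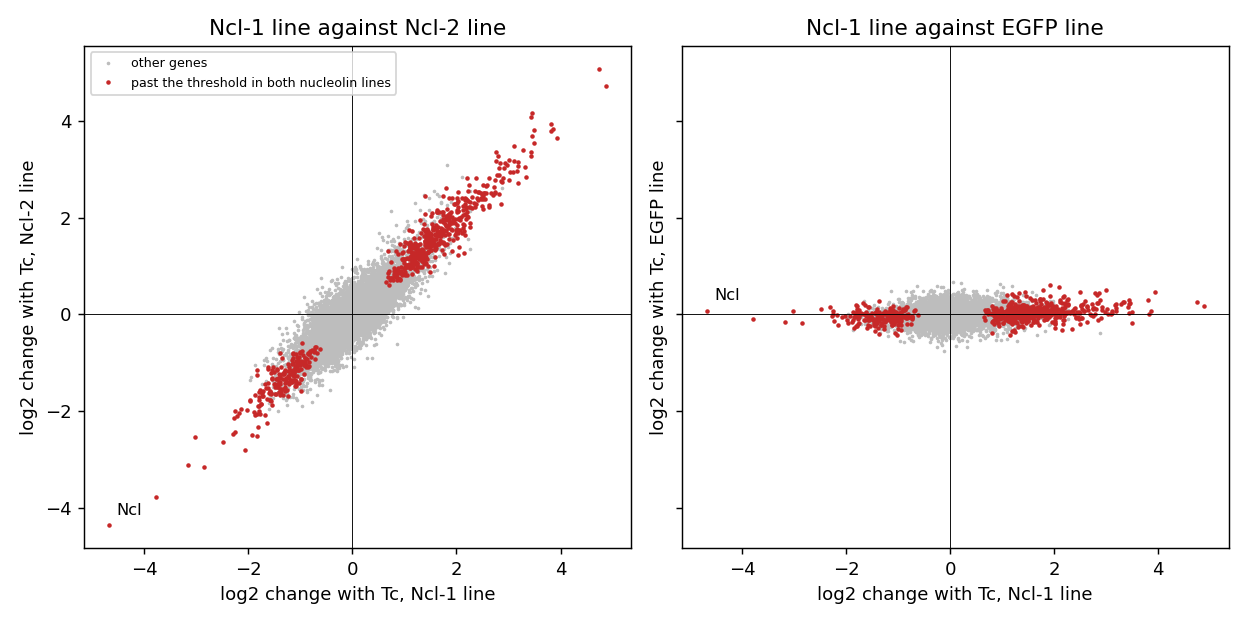
Log2 change with Tc of each of the 10557 genes in the Ncl-1 line (x axes) against that in the Ncl-2 line (left) or the EGFP line (right), with the 686 genes called in both nucleolin lines in red. The changes correlate at r = 0.892 on the left and 0.195 on the right.

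Set against the EGFP response, the mean nucleolin response singled out the same leading genes. Fas was higher by 3.88 ± 0.28 (SE, adjusted p = 6.4e-06 by limma), Cpz by 4.62 ± 0.42, Ms4a10 by 4.65 ± 0.46, Casp14 by 3.78 ± 0.36, Krt7 by 3.74 ± 0.58, and Svop, a gene of synaptic vesicles, by 3.36 ± 0.47. Ncl was lower at -4.59 ± 0.44 (adjusted p = 5.3e-05), Chac1 at -3.68 ± 0.40, Hopx at -2.68 ± 0.49, Notum at -2.54 ± 0.45 and the growth factor gene Gdf1 at -2.42 ± 0.29 (adjusted p = 0.00022). In all, 347 genes passed, 267 higher and 80 lower, and 1513 with the block (934 and 579). The count was 186 without EGFP -Tc replicate 2 and was also moved by more than 1.5 times without EGFP -Tc replicate 1 or EGFP +Tc replicate 2. Cdkn1a had 1.52 ± 0.47 (adjusted p = 0.099, and 0.0016 with the block).

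In this contrast 7 p53 targets of 34 were higher and none lower (4 without EGFP -Tc replicate 2, 12 adjusted over the list alone, 19 with the block; median 0.98, adjusted p = 9.1e-11, and adjusted p = 0.0039 with an estimated correlation). Replication genes had a median of -0.44 (Ccne1 and Pola2 lower of 42, 3 adjusted over the list alone, 10 with the block, adjusted p = 1.1e-05, and adjusted p = 0.0065 with an estimated correlation). Ccne1 was lower at -1.78 ± 0.37 (adjusted p = 0.014, but 0.052 without EGFP +Tc replicate 2), and that of Pola2 was lost without EGFP -Tc replicates 1, 2 or 3 or EGFP +Tc replicates 1 or 2 (0.054 to 0.0788). Stress response genes had a median of -0.44 (5 lower of 34, 10 adjusted over the list alone, 12 with the block, adjusted p = 1.1e-05, and adjusted p = 0.0082 with an estimated correlation), with Herpud1 at -1.33 ± 0.26. That median was -0.81 without EGFP -Tc replicate 3. The 5 were 2 without EGFP -Tc replicate 1 or EGFP +Tc replicate 2, and 3 without EGFP -Tc replicate 2, EGFP +Tc replicate 1 or Ncl-2 -Tc replicate 2. The sterol list had -0.47 (Scd2 lower of 21, 7 with the block, adjusted p = 0.00042, and adjusted p = 0.0232 with an estimated correlation). Scd2, a fatty acid desaturase gene rather than one of sterol synthesis, was at -1.80 ± 0.38.

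In the same contrast two-cell-stage genes had a median of 1.69 (Dppa3 higher of 13, 5 adjusted over the list alone, 7 with the block, adjusted p = 1.1e-05, and adjusted p = 0.275 with an estimated correlation), and trophectoderm genes 0.26 (Krt7 and Tfap2c higher of 13, 5 adjusted over the list alone, 4 with the block, adjusted p = 0.0045, and adjusted p = 0.275 with an estimated correlation). The two-cell median was 1.01 with no filter on detection, and 2 members were higher without Ncl-1 -Tc replicate 3 or Ncl-1 +Tc replicate 2. The trophectoderm median was 0.16 without EGFP -Tc replicate 1, 0.48 without EGFP -Tc replicate 3, 0.45 without EGFP +Tc replicate 1, and 0.61 without Ncl-1 +Tc replicate 1. It was 0.07 without Ncl-1 +Tc replicate 3 and 0.64 without Ncl-2 +Tc replicate 3. The value was 0.48 with no background correction and 0.46 with the authors' table. The Dppa3 call (2.33 ± 0.53, adjusted p = 0.022) was lost without EGFP -Tc replicate 1 (0.079), EGFP +Tc replicate 1 (0.071) or EGFP +Tc replicate 2 (0.06). Histone genes had 0.38 (0 of 48 by limma, adjusted p = 0.0403, and adjusted p = 0.691 with an estimated correlation), and this call was lost without 7 different arrays in turn, with the highest adjusted p, 0.674, without EGFP +Tc replicate 3. The others were EGFP -Tc replicates 1 and 2, Ncl-1 -Tc replicate 3, Ncl-1 +Tc replicate 3, Ncl-2 -Tc replicate 1 and Ncl-2 +Tc replicate 3. The histone median was 0.17 without EGFP -Tc replicate 1, 0.69 without EGFP -Tc replicate 3, 0.08 without EGFP +Tc replicate 3 and 0.25 without Ncl-1 +Tc replicate 3. It was 0.14 with array weights and 0.13 in replicates 1 and 2. Myc targets had -0.20 (Mthfd2 lower of 25, adjusted p = 0.0447, but 0.0572 with the block, where 4 were lower and 2 higher, and adjusted p = 0.322 with an estimated correlation). The call of the list Myc and growth targets, nucleolin lines minus EGFP line, was lost without EGFP -Tc replicate 3 (0.177), EGFP +Tc replicate 1 or 2, Ncl-1 -Tc replicate 1 or 2, Ncl-1 +Tc replicate 1, Ncl-2 -Tc replicate 2 or 3, or Ncl-2 +Tc replicate 1 or 3 (0.051 to 0.0908). The Myc median was -0.31 without Ncl-1 -Tc replicate 1 or Ncl-2 -Tc replicate 1, and 2 members were lower without EGFP +Tc replicate 3 or Ncl-2 +Tc replicate 3. The call of Mthfd2 (-1.58 ± 0.34) was lost without EGFP -Tc replicate 1 (0.058), EGFP -Tc replicate 2 (0.055) or EGFP +Tc replicate 2 (0.071). Ribosome biogenesis genes (median -0.31, adjusted p = 0.0659) and mitochondrial ribosomal proteins (median -0.19, adjusted p = 0.0726) passed with the block, at adjusted p = 0.0038 (4 lower) and 0.0488 (2 lower). Neither held with an estimated correlation (adjusted p = 0.385 and 0.691, and adjusted p = 0.409 and 0.89 with the block as well).

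The uninduced nucleolin lines already differed from the uninduced EGFP line. Dppa3 was lower at -3.05 ± 0.43 (SE, limma adjusted p = 0.0037) in the Ncl-1 line and -2.37 ± 0.43 (adjusted p = 0.019) in the Ncl-2 line, the latter call being lost without EGFP -Tc replicate 1 (0.091), EGFP -Tc replicate 3 (0.06) or Ncl-2 -Tc replicate 3 (0.067). Ms4a6d was higher at 2.69 ± 0.30 (adjusted p = 0.00076) and 2.45 ± 0.30 (adjusted p = 0.0018), and Adam32, a membrane protease-like gene of the testis, was higher at 2.26 ± 0.35 and 2.30 ± 0.35. Gal3st1, a glycolipid sulfotransferase, was lower at -1.95 ± 0.30 and -2.10 ± 0.30, and Aldh3a1, an aldehyde dehydrogenase, at -1.94 ± 0.26 (adjusted p = 0.0025) and -1.34 ± 0.26 (adjusted p = 0.024). Ncl did not differ, at 0.40 ± 0.36 and 0.06 ± 0.36. The Ncl-1 line differed in 104 genes (62 higher, 42 lower) and 910 with the block, and the Ncl-2 line in 98 (49 higher, 49 lower) and 1287 with the block. The counts fell to 16 and 15 without EGFP -Tc replicate 1, and leaving out any other EGFP -Tc array or any array of the uninduced nucleolin line compared moved each count by more than 1.5 times too. These comparisons share the EGFP arrays, so their overlap was not tested.

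Of the lists, germ cell genes were lower in both uninduced lines (Dppa3, Rhox9 and Rhox6 lower of 12 in each, medians -0.28 and -0.32, adjusted p = 0.0134 and 0.018), and so were trophectoderm genes (Rhox9 and Rhox6 lower of 13 in each, medians -0.47 and -0.29, adjusted p = 0.015 and 0.0402). Rhox6, chosen after its values were seen, was undetected in the uninduced nucleolin lines. None of these 4 calls held with an estimated correlation (adjusted p = 0.115, 0.15, 0.614 and 0.734) or with the block (0.103, 0.103, 0.103 and 0.121). With the block the germ cell counts were 5 lower and 2 higher in the Ncl-1 line and 4 lower and 1 higher in the Ncl-2 line. In the Ncl-1 line LIF and BMP response genes were higher (median 0.27, 0 of 19 by limma and 3 higher with the block, adjusted p = 0.0202, and adjusted p = 0.168 with an estimated correlation). Histone genes were lower (median -0.34, adjusted p = 0.0134, and adjusted p = 0.839 with an estimated correlation). Primitive endoderm genes (median -0.39, adjusted p = 0.0462) and mitochondrial ribosomal proteins (median -0.10, adjusted p = 0.0462) were also lower, and both calls were lost with the block (0.103 each, where 2 and 6 members were lower and 1 and 0 higher) and with an estimated correlation (adjusted p = 0.614 and 0.839). In the Ncl-2 line two-cell-stage genes were higher (Zscan4c and Gm428 higher and Dppa3 lower of 13, median 0.58, adjusted p = 0.0151), a call lost with the block (0.0784, where 5 were higher and 1 lower) and with an estimated correlation (adjusted p = 0.811). Gm428 was chosen after its values were seen. Zscan4c (3.04, adjusted p = 0.0313) belongs to a family of near-identical copies, and its call was lost without EGFP -Tc replicates 1, 2 or 3, EGFP +Tc replicate 2, or Ncl-2 -Tc replicates 1 or 2 (0.0502 to 0.142).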

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

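The tests of the EGFP response, of the ratio between both nucleolin lines, of the single-copy members, of the separate normalization and of the draws that swap Tc within pairs were chosen only after the result was seen.

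The response to Tc differed between the nucleolin lines and the EGFP line in 347 genes and 8 lists, tested as a difference of responses. Fas (3.88 ± 0.28) and Cpz (4.62 ± 0.42) led the genes. Among 100 draws of the Tc labels within each line, the real one included, 2 gave as many genes. The highest other count was 402, in the 1 draw that kept both nucleolin lines as they were and shuffled the EGFP line, and without that draw it was 314. For the 686 genes shared by both nucleolin lines 2 of the 100 draws gave as many. The highest other was 699, from the same draw, and 0 without it. For the 8 lists chance was not excluded, since 8 of the 100 draws gave as many and the highest other was 10. That draw kept 10 of the 12 nucleolin arrays as labelled, so part of the response stayed in it. The 5 draws that part all 9 pairs of arrays gave at most 0 genes, 0 shared genes and 9 lists apart from the real one, while the others put both arrays of at least 1 pair on the same side.

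Since the replicate numbers pair the arrays, a further 100 of the 256 possible draws, the real one included, swapped Tc only within pairs. As many genes came from 4 of them for the difference from the EGFP line (highest other 524) and from 4 for the shared genes (highest other 697), a share under 0.05 for both counts. The 3 other draws that reached these counts kept both nucleolin lines as they were and swapped pairs of the EGFP line, and without them the highest was 0 for each count. The draws thus set apart the Tc labels of the nucleolin lines. They do not set apart those of the EGFP line, since its real labels gave the lowest of the 4 counts against EGFP (347). For the lists 40 of the 100 gave as many (highest other 11), so chance was not excluded. The draws with 11 lists kept 8 of the 12 nucleolin arrays as labelled, and such draws keep part of the response. The share therefore does not measure how often chance alone would give as many lists.

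The responses of both nucleolin lines differed from each other in 2 lists, tested as a difference of responses: histone genes (median 0.33 higher in the Ncl-1 line) and respiratory chain genes (0.14). Neither held with an estimated correlation (adjusted p = 0.876 for both). For this difference limma called 0 genes, with 41 at an unadjusted p below 0.05 and 0 with the block (299 unadjusted). By chance 528 would be expected, so the test was conservative. All 100 draws gave at least that many genes, which a real count of 0 fixes in advance. Of these, 5 called any gene, with 2303 the highest and 3 above 1000. The 3 counts above 1000 point to a structure of the samples, which was not identified. All 3 draws above 1000 place the replicate 3 arrays on opposite sides in the nucleolin lines, but 14 draws do so and the rest of these called 0 genes. The other 2 that called genes, 499 and 485, do not. Each of these kept the real split of 1 nucleolin line and not that of the other. The response of 1 line to Tc thus entered the difference, although other draws that did so called 0 genes.

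Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For the Ncl-1 line the real split called 857 genes and the highest other 0 (1 split as large), and for the Ncl-2 line 964 and 0 (1 split). Without Tc, the Ncl-1 and Ncl-2 lines against EGFP gave 104 and 98 genes and the highest other 0 in each (1 split as large in each). The EGFP line gave 0 in all 10 splits. For the lists, 6 splits gave as many as the 8 in the Ncl-1 line (highest other 10), 4 as many as the 6 in the Ncl-2 line (highest other 9), and 10 as many as the 0 in the EGFP line (highest other 5). With a count of 0 this last share was fixed in advance. Of the 10 splits 4 part all 3 pairs. The other 3 of these swap Tc within 1 pair and gave at most 10, 8 and 3 lists, and the splits that leave 2 arrays of a pair together follow the replicate batch and gave at most 8, 9 and 5. The number of lists called at the preset correlation therefore does not by itself set the real split apart.

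Probes without a single gene symbol, which no comparison of genes used, also responded. Of 2784 such probes 107 changed in the Ncl-1 line (78 higher, 29 lower) and 143 in the Ncl-2 line (42 of them lower), against 0 by limma in the EGFP line (5 at an unadjusted p below 0.05). With the replicate block the counts were 520, 611 and 0. Both nucleolin lines shared 84 of them in the same direction and 0 in opposite directions. What these probes measure is not given in the sources used here.

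As a list, the 34 p53 targets shifted upward with Tc in both nucleolin lines, and the tables argue against each technical explanation tested. Of the 34, 13 passed the threshold as higher in each line, among them Fas, Mdm2 and Apaf1, and 1 as lower in the Ncl-1 line (23 and 24 higher with the replicate block). In the Ncl-2 line the 13 were 8 without Ncl-2 -Tc replicate 2. Tc or siRNA induction as such is argued against by the list's median of 0.0493 in the EGFP line, where at least 0.5 of the nucleolin medians would be needed, and an effect of 1 siRNA off its target by the ratio of 0.886 between the medians of both lines. Signal level is argued against by 10000 random lists matched on signal, whose highest median response was 0.32 against the 0.98 of the list. In other splits of the arrays the list's absolute median reached at most 0.42 and 0.47 against 1.10 and 0.97, although camera at the preset correlation called it in 6 and 5 of the other 9 splits. A response of p53 targets to loss of nucleolin is a hypothesis that these values leave open. The list was fixed before the data were examined, but its rise and the tests of its explanations come from the same data.

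As a list, two-cell-stage genes shifted upward with Tc in both nucleolin lines at the preset correlation and not with an estimated one (adjusted p = 0.406 and 0.23). Of 13 members 2 in the Ncl-1 line and 6 in the Ncl-2 line passed the threshold, or 7 and 10 with the replicate block, among them Dppa3. Those counts were 1 without Ncl-1 +Tc replicate 3 or Ncl-1 -Tc replicates 1 or 2, and 1 without Ncl-2 +Tc replicate 1. They were 5 without Ncl-1 +Tc replicate 2, 6 without Ncl-1 -Tc replicate 3, 2 without Ncl-2 -Tc replicates 2 or 3 and 3 without Ncl-2 +Tc replicate 2. Signal shared among multicopy paralogs as the whole source of the rise is argued against by the 4 single-copy members (Arg2, Dppa3, Tmem92 and Zfp352). Their median response was 1.90 against 0.91 for the 9 multicopy members. Whether the multicopy probes share signal cannot be told from this test, which compares only the size of the responses. Dppa3 was already lower in the uninduced nucleolin lines than in the uninduced EGFP line. By the test set for it, fluctuation between samples without knockdown may account for the rise. The smallest of the 6 paired rises of the list's median was 0.32, and the median's range among arrays without knockdown of the same replicate number reached 1.04. That range includes differences between the lines, which the paired rises do not. Within the EGFP line the paired rises with Tc were 0.20, 0.01 and 0.09, each below all 6 nucleolin rises. An effect of nucleolin loss also stays open.

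Replicate 3 stood apart from replicates 1 and 2 in all 6 groups. The authors' separate normalization as the whole cause is argued against by a gap of 36.1 on the first component that remained after all arrays were normalized together. A probe-specific difference of hybridisation or labelling may account for it. Across 3998 genes the replicate 3 differences of both probes of a gene correlated with r = 0.16, against 0.80 for the nucleolin response, a ratio of 0.196 (95% interval 0.154 to 0.243). The design names no biological difference of replicate 3, so no biological explanation was tested.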

How the results depend on the processing

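The batch term for replicate 3, the fits on replicates 1 and 2, the line-by-replicate block and the authors' table with the block were chosen only after the result was seen. Ncl kept its fall under every alternative run, between -5.20 and -4.35 in the Ncl-1 line and between -4.89 and -4.04 in the Ncl-2 line, with -0.14 to 0.30 in the EGFP line. The p53 list's median in the Ncl-1 line ranged from 0.96 to 1.17. Over all list results and alternatives 690 of 740 kept direction and call, 48 lost the call and 2 reversed. The list test used neither the array weights nor the altered prior variance. The 22 list results under each of these alternatives therefore could not lose a call, and they are among the 690. Of 14591 values of named genes 13068 stayed called or stayed uncalled, 635 lost the call, 887 gained it and 1 called value reversed. Among the 13068 were 97 uncalled values that changed sign.

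The counts here are, in order, of genes changed with Tc in the Ncl-1 line, genes changed with Tc in the Ncl-2 line, genes whose Tc response in the nucleolin lines differs from the EGFP line, genes different between Ncl-1 and EGFP lines without Tc, genes different between Ncl-2 and EGFP lines without Tc, and genes changed the same way in both nucleolin lines. The replicate block gave 2819, 2842, 1513, 910, 1287 and 1988. The batch term gave 2165, 2297, 1120, 617, 796 and 1558, and the authors' table with the block 2437, 2553, 1204, 735, 957 and 1711. Replicates 1 and 2 with the block gave 2056, 2612, 1254, 724, 689 and 1448, and array weights 4736, 5993, 2974, 3205, 3569 and 3611. The line-by-replicate block gave 3895, 3845, 2347 against EGFP and 2727 shared. Replicates 1 and 2 alone gave 1694 in the Ncl-2 line, 642 against EGFP, and 242 and 245 between the uninduced lines. Detection p under 0.01 on all arrays, which leaves fewer genes, gave 495, 541, 188, 66 (Ncl-1 against EGFP without Tc) and 397 shared. The blocks take out the spread between replicates; for array weights the cause was not tested. The block changed calls and counts as given beside the results named in the text, and no other list call in the contrasts with Tc.

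Of genes whose Tc response differs between the Ncl-1 and Ncl-2 lines there were 994 with array weights and 1 each with no background correction, replicates 1 and 2 alone, and these with the block. The EGFP line had 1 gene with array weights and 1 list with cyclic loess. A fit on the 6 arrays of a line alone, with fewer arrays, called 217 genes changed with Tc in the Ncl-1 line and 455 genes changed with Tc in the Ncl-2 line. Counting as shared the genes called against EGFP with the same sign in both nucleolin lines, with no call needed in either line, gave 347. These were all the genes called against EGFP. With an estimated correlation 4 lists stayed in the Ncl-1 line and 4 against EGFP. Cyp2b23 reversed in the Ncl-2 line with array weights (-0.58), and the median of the list trophectoderm, Ncl-1 line, reversed with replicates 1 and 2 alone and with the block added (-0.057 each, neither past the test). The cause of these was not tested.

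Of the lists called at the preset correlation, other alternatives ended the call as follows (adjusted p). In the Ncl-1 line ribosome biogenesis reached 0.0518 without background correction, 0.0765 with cyclic loess and 0.0545 with the authors' table, and the list histone genes, Ncl-1 line, 0.0747 with replicates 1 and 2 alone (0.0691 with the block), where the probe of each gene was chosen anew on 12 arrays. The list histone genes, nucleolin lines minus EGFP line, reached 0.169 and 0.156 there, and the list Myc and growth targets, nucleolin lines minus EGFP line, 0.0572 with the block and 0.0571 with the line-by-replicate block. Trophectoderm genes reached 0.265, 0.116 and 0.135 (Ncl-1, Ncl-2 and against EGFP) with detection p under 0.01, and the list trophectoderm, Ncl-1 line, 0.0694 with the authors' table and the block.

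Leaving out each array in turn gave 525 to 925 genes in the Ncl-1 line, 539 to 1057 in the Ncl-2 line, 0 to 0 in the EGFP line, 186 to 401 against EGFP, 0 to 0 between the nucleolin responses, 16 to 126 and 15 to 120 between the uninduced lines, and 454 to 700 shared. The lists numbered 6 (without Ncl-1 +Tc replicate 3) to 10 (without Ncl-1 -Tc replicate 3) in the Ncl-1 line, 6 to 9 (without Ncl-2 -Tc replicate 1) in the Ncl-2 line, 0 to 4 in the EGFP line, and 7 (without EGFP +Tc replicate 2) to 10 (without Ncl-1 +Tc replicate 3) against EGFP. Arrays that moved a count by more than 1.5 times are named beside the count. As these fits had no block, leaving out 1 array also mixed the difference between replicates into the response to Tc. The planned chip block was not run, since chip names were not used here. Signal over background limits what can be seen: 40.0% to 46.4% of the probes were detected per array.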

Other observations

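All tests and gene sets in this part were chosen only after the result was seen.

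Of 9 measured genes of secreted Wnt ligands 5 in the Ncl-1 line and 6 in the Ncl-2 line rose with Tc and 0 fell (7 and 8 higher with the replicate block). The 5 were 3 without Ncl-1 -Tc replicates 2 or 3 or Ncl-1 +Tc replicates 1 or 3. Wnt5a rose by 3.18 ± 0.34 (SE, n = 3 per group, limma adjusted p = 3.4e-05) in the Ncl-1 line and by 2.71 ± 0.34 (adjusted p = 0.00013) in the Ncl-2 line. Wnt3a, which acts in the primitive streak, rose by 3.11 ± 0.46 and was at least 9.56-fold higher, Wnt7b was at least 3.03-fold and 4.05-fold higher, and Wnt8b at least 2.60-fold and 2.15-fold. Wnt10a, Wnt4 and Wnt5b passed in neither line, and Wnt5b had -0.02 and -0.18. Among 159 families of genes with a common symbol stem, the Wnt family had medians of 1.67 and 1.64 (camera adjusted p = 5.0e-06 and 1.4e-06), and adjusted p = 0.611 and 0.442 with an estimated correlation, so the family as a group rests on the preset correlation. Both medians are fitted values of Wnt8b, which was undetected without Tc in both lines. With the 3 and 6 members undetected without Tc set to their bound the medians were 1.42 and 1.45. Such members had little room to fall, and a probe could be kept for its signal with Tc alone. The absence of falling members and the test of the family may therefore partly follow the detection filter. The family was not tested without that filter. Against the EGFP response 8 of 9 members were positive under each of 4 scalings. The size depended on the scaling. The family's median was 1.52 as processed here, 1.37 with cyclic loess, 2.95 without background correction and 3.01 with the authors' table.

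Pramel genes, a multicopy family of the germ line and early embryo, had medians of 1.17 and 1.63 (1.17 and 1.48 with the 1 undetected member at its bound) over 12 members (adjusted p = 0.0026 and 7.7e-05, and adjusted p = 0.763 and 0.442 with an estimated correlation). The family's call in the Ncl-1 line was lost without Ncl-1 -Tc replicate 1 (adjusted p = 0.0507). Of the 12 members 2 and 7 rose (8 and 9 with the block). The 2 were 0 without EGFP -Tc replicates 1 or 2, EGFP +Tc replicates 1 or 2, Ncl-1 -Tc replicates 1 or 2, Ncl-1 +Tc replicate 1 or Ncl-2 -Tc replicate 2. They were 1 without Ncl-1 +Tc replicate 3, Ncl-2 -Tc replicate 1 or Ncl-2 +Tc replicate 2, and 5 without Ncl-1 -Tc replicate 3. The 7 were 0 without Ncl-2 +Tc replicate 1, 2 without Ncl-2 -Tc replicate 2 or Ncl-2 +Tc replicate 2, 3 without Ncl-2 -Tc replicate 3 and 4 without Ncl-2 -Tc replicate 1. Against the EGFP response 11 of 12 were positive under each of 4 scalings. The median was 1.42 as processed here, 1.34 with cyclic loess, 1.93 without background correction and 1.88 with the authors' table. Their copies share sequence, so single members are uncertain. Without Tc, Pramel20 had a difference from the EGFP line of 1.87 (adjusted p = 0.112) in the Ncl-1 and 2.42 (adjusted p = 0.0347) in the Ncl-2 line, and Pramel16, chosen after its values were seen, of 1.93 (adjusted p = 0.0736) and 2.24 (adjusted p = 0.0347). Of these 4 differences those of the Ncl-2 line passed the threshold. The Pramel20 call was lost without any uninduced EGFP or Ncl-2 array, EGFP +Tc replicates 1 or 2, or Ncl-2 +Tc replicate 2 (0.0508 to 0.145), and Pramel16 was not run this way.

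Below background on all 6 uninduced nucleolin arrays and detected on all 6 induced ones were 46 genes, 23 of them also below background on all EGFP arrays, and 7 showed the reverse. Examples, chosen after their values were seen, are the neuropeptide gene Npy (at least 2.76-fold and 2.57-fold higher), Sec14l3 (at least 5.85-fold and 5.33-fold) and Serpina3n, an acute-phase protease inhibitor (at least 3.30-fold and 3.51-fold). By the same measure within 1 line, 112 genes appeared and 37 disappeared in the Ncl-1 line, 123 and 31 in the Ncl-2 line, and 3 and 14 in the EGFP line.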
